A study of Bacillus subtilis with 12 samples.

How the data were processed

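The labels describe RNA from 12 cultures of Bacillus subtilis BSB1, 3 biological replicates of each of 4 conditions, harvested at an optical density of 1.0, with 10 µg of total RNA per labelling. Each sample was labelled with Cy3 and hybridised to its own Agilent tiling array. The deposited files are the scanner outputs of Agilent Feature Extraction 11.5.1.1, per the submitters' processing notes, and hold 387021 spots per array. The column used is the processed signal, an intensity on a linear scale that Feature Extraction had corrected for background, per the file headers, before the arrays were put on a common scale. No spot was saturated, and 87 to 631 spots per array were marked as outliers and left out. The array design assigns 180746 probes to 5942 features, which are locus tags or numbered segments without annotation, and leaves 202461 probes unassigned. The unassigned probes entered the scaling and the test of antisense signal, and no other comparison. The design lists 3153 control spots and 630 spike-in spots, and 31 probes carried no name.

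For each array, log2 of the processed signal was taken and the 75th percentile over its 383238 non-control probes was subtracted. Each spot counted as a separate probe, and spots of 1 probe were not averaged, although this had been planned. A feature's value was the median over its probes. There were 23 probes per feature and 33 per protein-coding gene in the median, and 349 features had 1 probe. Features were tested if at least 50% of their probes were well above background on all 3 arrays of at least 1 group. Features with no probe well above background on any array of a group numbered 19 in control, 16 in GB, 27 in NaCl and 52 in NaCl+GB, and a change against such a group is given as a bound. The bound sets the brighter group's mean against the dim group's mean of, per array, the higher of the feature's own value and the lowest signal among probes well above background. Gene symbols came from a table of RefSeq genes of assembly ASM904v1, which matched 4407 of 4417 locus tags, and 99.99% of the probes of matched features lay inside that table's gene coordinates. The array's own genome build is not given in the sources used here, so no reference coordinates are printed. The names of segments carry the coordinates of the array design.

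The group comparisons used limma 3.58.1 in R 4.3.3, with the package data.table, version 1.17.8, for reading files. All 12 arrays entered 1 fit with a mean per group, so that the contrasts shared 1 estimate of the spread. A feature was called changed when its Benjamini-Hochberg adjusted p over the 5860 tested features was under 0.05 and its change at least 2-fold. The contrasts were NaCl vs control, GB vs control, NaCl+GB vs NaCl, NaCl+GB vs control and the interaction of both factors. These contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The contrast NaCl+GB vs GB was added after the scan days had been seen. The count of reversals asks how many features called in NaCl vs control were called in the opposite direction in NaCl+GB vs NaCl. The comparisons that share arrays were set beside 20 simulated sets of unchanged groups and beside the overlap of independent lists.

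Genes were chosen for naming by a fixed rule, and the text names part of those it takes. It takes, per contrast, the 10 largest increases and 10 largest decreases among called genes with a symbol that were above background (5 and 5 for the interaction), and every measured member of the lists for osmoprotectant uptake, glycine betaine synthesis from choline and proline synthesis. From each other list with at least 3 called members it takes the 2 largest changes in each direction. It adds sigB, gsiB, hag, dhbB and katA, and the 3 largest increases and decreases among called segments in the first 3 contrasts. gapB in GB vs control, dltC, dltD and dltE in NaCl vs control, the LexA regulon genes and the genes with antisense signal lie outside the rule and were chosen after their values were seen.

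The 32 gene lists were osmoprotectant uptake, glycine betaine synthesis from choline, proline synthesis, proline catabolism, potassium and sodium transport, mechanosensitive channels, the SigB general stress regulon, the SigW regulon, the SigM regulon core, iron acquisition (Fur regulon), motility and chemotaxis, biofilm matrix, poly-gamma-glutamate synthesis, extracellular proteases, competence, sporulation, ribosomal proteins, glutamate and nitrogen metabolism, the tricarboxylic acid cycle, glycolysis and gluconeogenesis, synthesis of histidine, arginine, branched-chain and sulfur amino acids, purine and pyrimidine synthesis, class I and III heat shock, the PerR regulon, fatty acid synthesis and desaturation, cell wall and teichoic acid synthesis, the PBSX prophage, tryptophan and aromatic amino acid synthesis, and respiration and fermentation. The listed names proG, comS and aroD were not matched. limma's camera tested each list against all other features with a preset correlation of 0.01, adjusted over the 160 tests of 32 lists and 5 contrasts, and over 32 for the added contrast. All 69 calls of the 160 were lost when camera estimated the correlation between genes, so that adjusted p stands beside each result. Counts of called members were also adjusted over the list alone, and for the 32 lists were the same except where the text gives both. In respiration and fermentation this count was 2 rather than 3 genes higher in NaCl+GB vs control. In no called list of the 5 contrasts did the median, mean and test differ in sign. The lists SPbeta prophage and ICEBs1 were added after values had been seen and were adjusted over their own 12 tests.

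The files show 6 slides and 4 scan days. Control replicate 2 and NaCl replicate 2 were on slide 1 and scan 1. The other control arrays were on slide 2 and the other NaCl arrays on slide 3, both scan 2. GB replicates 2 and 3 were on slide 4 and NaCl+GB replicates 2 and 3 on slide 5, both scan 3, and replicate 1 of both groups on slide 6 and scan 4. Scan day or slide entered as a fixed block where it held arrays of both groups and otherwise as a random block (duplicateCorrelation, with correlations of 0.326 for slide and 0.281 for scan day). The labels number the replicates alike in every group and do not say what a number shares. The deviations of same-numbered arrays from their group means correlated at 0.56, 0.16 and 0.57 between GB and NaCl+GB, and there each of the 6 arrays correlated best with its own number, so the numbers were taken to pair these arrays, and a replicate block called 1111 features in place of 1072 in NaCl+GB vs GB. No other pair of groups passed, although control and GB, without a shared slide or scan day, gave 0.44, -0.09 and 0.57. Number 1 of GB and NaCl+GB shared slide 6 and scan 4, which could also give its correlation. Control and NaCl gave 0.42 for number 2, on slide 1 and scan 1, and 0.08 and 0.01 for numbers 1 and 3.

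The procedure was tested on simulated data for NaCl vs control with 5860 features and 10 sets in which 200 features were changed. It recovered 91% of changes of 1.5 and 99.1% of changes of 3 on the log2 scale, with a mean of 1.9 false calls, and a mean of 0.1 calls when nothing was changed. Alternatives were normexp background correction with an offset of 50, quantile, median, spike-in and detected-probe scaling, the mean over probes, other filters, other thresholds, a trended robust spread, fits of the 2 groups alone, blocks, and leaving out each array. normexp had been planned on the mean signal, which was not used here, and was run on the median signal. The submitters' value table was planned as an alternative by feature name. Its row numbers matched no column of the scanner files used here, so it entered only as counts of unnamed rows, as log2 of the value plus 0.05. Each of its 12 columns had a median of 1.00 over 5737 values, and how its values were scaled, centred and directed stays unknown. Alternatives chosen after the files were seen were the random blocks, leaving out both scan 4 arrays, the counts of that table, scan day as a block and left-out arrays on gene lists, and all settings of NaCl+GB vs GB. Unassigned probes were examined only for signal on the strand opposite to a gene.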

Results

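Bacillus subtilis BSB1, a derivative of the laboratory strain 168 that makes its own tryptophan, was grown in Spizizen's minimal medium at 37 °C under 4 conditions. These were the medium alone (control), the medium with 1 mM glycine betaine (GB), with 1.2 M NaCl (NaCl), and with both (NaCl+GB). Glycine betaine is a compatible solute, a small organic molecule that bacteria accumulate at high salinity. Total RNA from 3 cultures per condition, described in the labels as biological replicates, was labelled with Cy3 and hybridised to 12 one-colour tiling arrays. Each array carried 383238 non-control probes, of which 66.4 to 76.2% were well above background, and the 75th percentile of their processed signal ran from 2481 to 4450. The probes covered 5942 features, and 5860 of them were tested, made up of 4381 annotated genes and 1479 unannotated transcribed segments. With 3 arrays per group, the number of arrays limits the precision of each value. Replicates of a group correlated at r = 0.975 to 0.995 across features, which are not independent replicates. The first principal component held 65.3% of the variance and the second 20.4%. The arrays without glycine betaine were scanned on scan days 1 and 2, and those with it on scan days 3 and 4, so any comparison of cultures with and without glycine betaine is also a comparison of scan days.

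**Figure D1:**
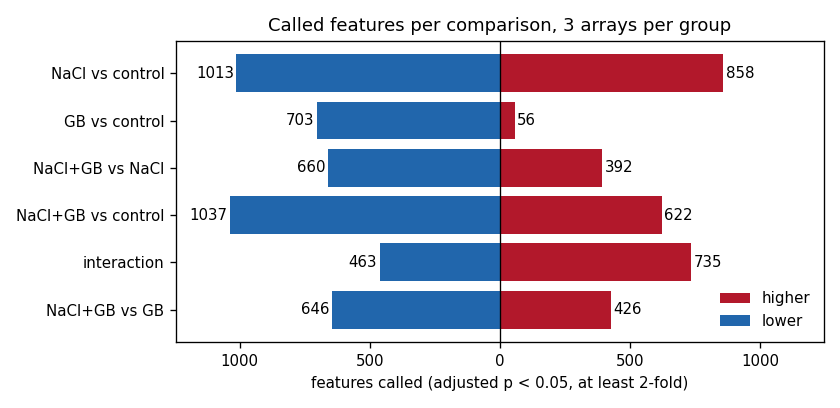
Number of features called higher (right, red) or lower (left, blue) in each comparison of the 4 conditions, with 3 arrays per condition. NaCl vs control gave 858 higher and 1013 lower, and GB vs control gave 56 higher and 703 lower.

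High salinity, the first factor of the design, changed 1871 of the 5860 tested features relative to the control, 858 higher and 1013 lower. Among annotated genes 660 rose and 698 fell. Some of the genes that move or make compatible solutes rose. opuE (BSU06660), which encodes a proline transporter, rose by 3.84 (SE 0.34, limma adjusted p = 1.75e-06), where all values of change are log2 fold changes from 3 arrays per group. proH and proJ, the genes of the osmotically controlled proline synthesis route, rose by 2.69 (SE 0.17) and 2.71 (SE 0.16), while proA, proB and proI stood at -0.21 to 0.38 and were not called, proB with a limma adjusted p of 0.00704 but within 2-fold. The glycine betaine importer genes opuAA, opuAB and opuAC rose by 1.08 to 1.19, and opuBA and opuBB of the choline importer by 1.15 and 1.16 (SE 0.12 to 0.14, limma adjusted p of at most 3.29e-05). opuBC and opuBD at 0.88 each, opuD at 0.57, and the 4 opuC genes at -0.63 to -0.46 lay within 2-fold of the control. The limma adjusted p of the opuC genes was 0.00407 to 0.0241. In all, 6 of 13 osmoprotectant uptake genes rose and none fell, and camera did not call the list (camera adjusted p = 0.0589, and adjusted p = 0.780 with an estimated correlation). Of the genes for making glycine betaine from choline, gbsA, gbsB and opcR rose by 2.10 to 2.38 and gbsR stood at 0.62 (camera adjusted p = 0.00670, and adjusted p = 0.540 with an estimated correlation). The proline synthesis list, with 2 of 5 genes higher, was not called (camera adjusted p = 0.0959, and adjusted p = 0.688 with an estimated correlation). opuBC and opuBD were called with median scaling, at 1.04 each, and opuBD also when probes were averaged by their mean. With slide as a block, which leaves 1 array of each group on slide 1 to carry the difference, opuBC stood at 1.03. With spike-in scaling opuAB, opuAC, opuBA and opuBB came to 0.95, 0.92, 0.99 and 1.00 and missed the 2-fold minimum, and opuAC also missed it without NaCl replicate 2, at 0.999.

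**Figure D2:**
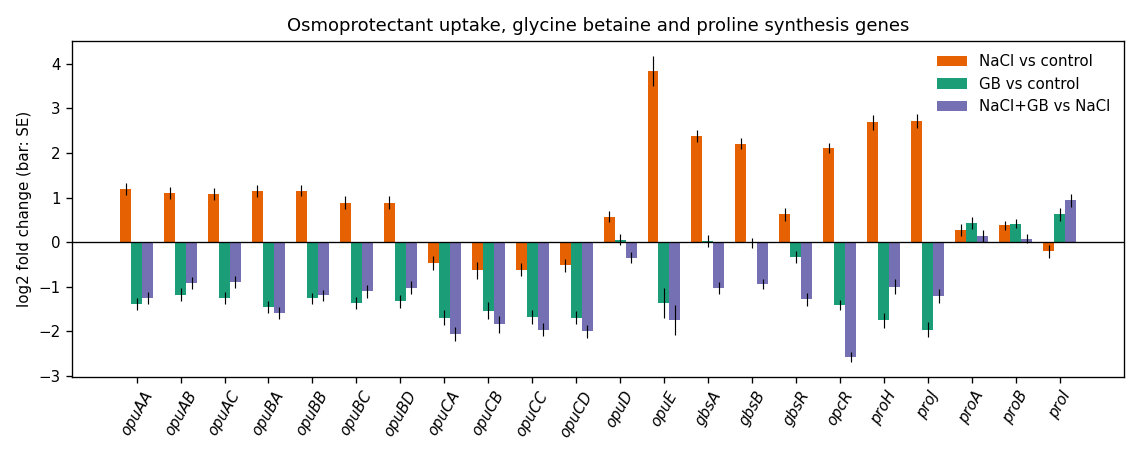
Log2 fold changes (y axis) of the genes for osmoprotectant uptake, glycine betaine synthesis from choline and proline synthesis (x axis) in 3 comparisons, with bars of 1 standard error and 3 arrays per group. opuE stood at 3.84 in NaCl vs control, -1.37 in GB vs control and -1.76 in NaCl+GB vs NaCl.

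Stress, iron and prophage genes rose with salt. In the SigB general stress regulon 70 of 104 genes rose and 5 fell (camera adjusted p = 1.83e-07, and adjusted p = 0.694 with an estimated correlation), with yjgB at 5.53 (SE 0.86), ydaD at 5.47 (SE 0.90) and gsiB at 4.13 (SE 0.91) among those that rose, and clsB at -4.55 (SE 0.33) and yfhD at -2.36 (SE 0.29) among those that fell. Of the iron acquisition genes under the repressor Fur, 18 of 29 rose (camera adjusted p = 4.49e-07, and adjusted p = 0.683 with an estimated correlation), led by genes for the siderophore bacillibactin, dhbA at 4.06 (SE 0.18), dhbC at 3.94 (SE 0.17) and dhbB at 3.86 (SE 0.21). Of the genes of the defective prophage PBSX, 25 of 26 rose (camera adjusted p = 1.71e-12, and adjusted p = 0.683 with an estimated correlation), xtmB by 3.29 (SE 0.16) and xpf by 3.26 (SE 0.25). The largest increases outside these lists included blyA (BSU21410), a cell wall amidase gene of the prophage SPbeta, at 5.71 (SE 0.31, limma adjusted p = 4.77e-08), and its neighbour bhlA at 5.36 (SE 0.42). Proline catabolism genes rose in 3 of 4 cases (camera adjusted p = 0.00236, and adjusted p = 0.505 with an estimated correlation), with putB at 4.43 (SE 0.13) and putC at 3.96 (SE 0.13). Of the potassium and sodium transport genes 11 of 18 rose and 1 fell (camera adjusted p = 0.00189, and adjusted p = 0.539 with an estimated correlation), with khtU and khtT of a potassium exporter at 2.07 and 2.04. The gene that fell, nhaC, stood at -1.18 (SE 0.39) and was no longer called without control replicate 1 or 2 or without NaCl replicate 2 or 3, at -1.17 to -1.15 with limma adjusted p of 0.0516 to 0.0549. Of the sulfur amino acid genes 4 of 25 rose (camera adjusted p = 0.0335, and adjusted p = 0.770 with an estimated correlation), among them the cystine uptake genes tcyJ at 2.62 and tcyK at 2.59. The unannotated segment new_2263262_2263488 rose by 6.64 (SE 0.34).

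Genes of the biofilm matrix and of sporulation fell. Of the matrix genes 21 of 22 fell (camera adjusted p = 6.71e-15, and adjusted p = 0.0832 with an estimated correlation). tasA (BSU24620), which encodes the matrix fibre protein, fell from 3.59 ± 0.08 to -3.92 ± 0.29 (mean log2 signal relative to the array's 75th percentile ± SD, n = 3), a change of -7.51 (SE 0.14, limma adjusted p = 9.46e-11), and sipW, whose product processes it, changed by -7.16 (SE 0.21). Of the sporulation genes 23 of 29 fell (camera adjusted p = 1.15e-08, and adjusted p = 0.688 with an estimated correlation), with spoIIQ at -4.64 (SE 0.32) and spoIIIAH at -4.59 (SE 0.29). The later sporulation genes spoIIID at -7.60 (SE 0.60), cotNE at -7.42 (SE 0.25) and cotZ at -7.40 (SE 0.28) were among the 10 largest decreases. Motility and chemotaxis genes fell in 16 of 52 cases (camera adjusted p = 6.46e-08, and adjusted p = 0.688 with an estimated correlation), with the chemoreceptor gene tlpA at -1.96 and the autolysin gene lytD at -1.69, while the flagellin gene hag stood at -0.74 (limma adjusted p = 0.0164), within 2-fold, and at -1.02 with slide as a block, from 1 array of each group. The SigM core list shifted down with 3 of 22 genes lower (camera adjusted p = 0.0157, and adjusted p = 0.688 with an estimated correlation), abhA at -2.46 and bcrC at -1.40 among them. The histidine synthesis list shifted down with 1 of 8 genes past the 2-fold minimum (camera adjusted p = 0.0336, and adjusted p = 0.710 with an estimated correlation). Single genes outside called lists included katA, the vegetative catalase, at -2.20 (SE 0.13), glnH of a glutamine importer at -4.32, and dltA and dltB, which attach D-alanine to teichoic acids, at -2.20 and -2.06.

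All counts of called features are from limma (adjusted over 5860 features by Benjamini-Hochberg, at least 2-fold). Median and spike-in scaling shifted all features by a median of 0.15 and -0.17, against -0.01 with the scaling used throughout. With them 1030 features were higher and 890 lower, and 709 and 1172, so which direction had more calls depended on the scaling. Both groups were present on scan days 1 and 2. Within each of these days 100% of the called features, which were chosen on the same arrays, kept their direction, the 2 sets of changes correlated at r = 0.979 across features, and with scan day as a block 1873 features were called. The 12 called lists kept their call with scan day as a block and their direction on both days, with medians that differed by at most 0.22, for example -4.24 and -4.17 for the biofilm matrix list and 1.81 and 1.82 for the SigB list on scan days 1 and 2. Without NaCl replicate 2 the sulfur amino acid list lost its call, and without NaCl replicate 1 the histidine list (camera adjusted p = 0.0626 and 0.0562). Osmoprotectant uptake was called without control replicate 3 or NaCl replicate 1 or 3 (camera adjusted p = 0.0403 to 0.0496). The competence list, with a median of -0.32, was not called (camera adjusted p = 0.175). Without NaCl replicate 1 it was called lower, at -0.59 (camera adjusted p = 0.0115).

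Glycine betaine without added salt, the second factor, went with 56 features at least 2-fold higher and 703 at least 2-fold lower than in the control. Without the fold minimum 1317 were higher and 1116 lower, so the downward balance held only among the larger changes. Genes for the uptake of osmoprotectants fell together, in 12 of 13 cases (camera adjusted p = 2.83e-08, and adjusted p = 0.664 with an estimated correlation). opuCA to opuCD fell by 1.54 to 1.70 on the log2 scale, and opuCD (BSU33800) stood at -1.70 (SE 0.14, limma adjusted p = 4.91e-06). The opuA genes stood at -1.38 to -1.18, the opuB genes at -1.47 to -1.26 and opuE at -1.37, and opuD at 0.05 was not called. opuAB reached only -0.95 with median scaling. opcR, which encodes a regulator of choline uptake, fell by 1.41 (SE 0.11), whereas gbsA, gbsB and gbsR stood at -0.33 to 0.02 and were not called (camera adjusted p = 0.204, and adjusted p = 0.688 with an estimated correlation for that list). proH and proJ fell, at -1.75 (SE 0.17) and -1.97 (SE 0.16), while proA, proB and proI stood at 0.41 to 0.63 without a call (camera adjusted p = 0.792, and adjusted p = 0.934 with an estimated correlation).

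Sporulation genes fell as well. Of the listed sporulation genes 23 of 29 fell (camera adjusted p = 9.71e-13, and adjusted p = 0.673 with an estimated correlation), with spoIIQ at -2.96 (SE 0.32) and spoIIIAF at -2.93 (SE 0.32). The largest decreases were those of the coat and late sporulation genes, cotNE at -5.12 (SE 0.25, limma adjusted p = 1.58e-07), cotM at -4.94 (SE 0.23) and cotF at -4.73 (SE 0.28), together with yisZ at -5.01 and yitB at -4.94. glnH fell by 3.37 (SE 0.36). Competence genes shifted up, with 6 of 20 called higher (camera adjusted p = 5.05e-05, and adjusted p = 0.688 with an estimated correlation), among them comK, the competence regulator, at 1.30 (SE 0.22) and nin at 1.23 (SE 0.24). rocA and rocG, which act in arginine degradation, rose by 1.17 and 1.13, and rocG stood at 0.95 when probes were averaged by their mean. The motility list shifted up by a median of 0.55 with none of its 52 genes past the 2-fold minimum (camera adjusted p = 3.19e-09, and adjusted p = 0.688 with an estimated correlation), and histidine synthesis genes by 0.93 with 2 of 8 called (camera adjusted p = 0.00670, and adjusted p = 0.688 with an estimated correlation). The lists of ribosomal proteins, glycolysis, arginine, branched-chain, sulfur and aromatic amino acids, purines and pyrimidines, and fatty acids also shifted up, by medians of 0.32 to 0.59 (camera adjusted p = 6.94e-07 to 0.0486, and adjusted p = 0.688 to 0.710 with an estimated correlation). In these 8 lists no gene was called higher, and 1 of the glycolysis list, gapB, was called lower at -1.25. The fixed examples gsiB, sigB, katA and hag stood at -0.25 to 0.57 and were not called, and dhbB fell by 1.26. The iron acquisition list as a whole was not called, with 8 of 29 genes lower (camera adjusted p = 0.638, and adjusted p = 0.934 with an estimated correlation). The segment new_2037498_2037600_c fell by 5.17 on the log2 scale (SE 0.30).

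No scan day held both groups, so scan day and glycine betaine cannot be told apart here by a block, and with scan day or slide as a random block 755 and 747 features were called. With detected-probe scaling 29 features were higher and 757 lower. With median scaling 196 were higher and 608 lower, a share of 24.4% higher against 7.38%, and all features then shifted by a median of 0.34, against 0.11 with the scaling used throughout and 0.12 with quantile normalization. The aromatic amino acid list lost its call without control replicate 1 or 2, GB replicate 2 or 3 or NaCl+GB replicate 1 (camera adjusted p = 0.0509 to 0.0895).

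At high salinity, glycine betaine went with 392 features higher and 660 lower than in NaCl alone. Without the fold minimum these were 1571 and 1498. The genes of the biofilm matrix and of competence rose together. Of the matrix genes 19 of 22 rose (camera adjusted p = 3.05e-15, and adjusted p = 0.0832 with an estimated correlation), with sipW at 4.29 (SE 0.21), tasA at 3.85 (SE 0.14, limma adjusted p = 2.71e-08) and tapA at 3.58 (SE 0.15). All 20 competence genes rose (camera adjusted p = 5.44e-11, and adjusted p = 0.688 with an estimated correlation), with comGG at 3.21 (SE 0.24, limma adjusted p = 2.22e-06) and comGF at 2.96 (SE 0.23). comGG stood at 0.91 ± 0.47 in NaCl and at 4.13 ± 0.35 in NaCl+GB (mean log2 signal relative to the 75th percentile ± SD, n = 3). The largest increases belonged to gamP and gamA, which take up and use glucosamine, at 4.85 (SE 0.17, limma adjusted p = 2.50e-08) and 4.48 (SE 0.15), to tagC (BSU35770), known to be induced by DNA damage, at 4.50 (SE 0.21), and to the mannose transporter gene manP at 3.25 (SE 0.23).

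Genes for osmoprotectants and general stress fell. Of the uptake genes 10 of 13 fell (camera adjusted p = 2.72e-07, and adjusted p = 0.673 with an estimated correlation), with the opuC genes at -2.07 to -1.84, the opuB genes at -1.59 to -1.02, opuAA at -1.26 and opuE at -1.76 (SE 0.34). opuAB at -0.92, opuAC at -0.89 and opuD at -0.35 were not called. opcR fell by 2.57 (SE 0.11), gbsR by 1.29 and gbsA by 1.04, and gbsB stood at -0.94 without a call (camera adjusted p = 0.00189, and adjusted p = 0.505 with an estimated correlation). proH and proJ fell by 1.01 and 1.21, while proA, proB and proI stood at 0.07 to 0.93 (camera adjusted p = 0.759, and adjusted p = 0.919 with an estimated correlation). Some of these calls lay at the 2-fold minimum and ended when 1 array was left out: opuBC without NaCl+GB replicate 2, opuBD without NaCl replicate 2 or NaCl+GB replicate 2, gbsA without NaCl replicate 2 or NaCl+GB replicate 1, and proH without replicate 2 or 3 of either group. Over the alternatives that ended the calls the smallest change was -0.86. gbsB was called without NaCl+GB replicate 3 (limma adjusted p = 2.26e-04) and with detected-probe or spike-in scaling, at -1.02 and -1.04. With quantile normalization opuAB, opuAC and proI were called, at -1.14, -1.10 and 1.01, and with median scaling proI, at 1.08. All 4 proline catabolism genes fell (camera adjusted p = 0.00191, and adjusted p = 0.505 with an estimated correlation), putP by 1.45 and putB by 1.40. In the SigB regulon 39 of 104 genes fell and none rose (camera adjusted p = 2.99e-06, and adjusted p = 0.715 with an estimated correlation), with yhxD at -2.74 (SE 0.73), while gsiB at -1.88 (SE 0.91) and sigB at -0.67 (SE 0.30) were not called. Without GB replicate 1, which enters only the shared spread, gsiB passed with a limma adjusted p of 0.0435. The largest decreases also included yqiH at -3.86 (SE 0.21), ispA (BSU13190), which encodes an intracellular protease, at -3.73 (SE 0.16), blyA at -3.57 (SE 0.31) and acoA of acetoin breakdown at -3.28 (SE 0.28).

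Some biosynthetic lists moved up and others did not. The arginine, branched-chain and sulfur amino acid lists stood at medians of -0.01 to 0.15 and were not called (camera adjusted p = 0.507 to 0.891, and adjusted p = 0.916 to 0.992 with an estimated correlation). Histidine synthesis genes rose in 8 of 8 cases (camera adjusted p = 9.83e-04, and adjusted p = 0.688 with an estimated correlation), with hisZ at 1.49 and hisG at 1.35. Of the purine and pyrimidine genes 16 of 25 rose (camera adjusted p = 1.26e-07, and adjusted p = 0.539 with an estimated correlation), with purA at 1.71 and purB at 1.35. Of the PBSX genes 10 of 26 rose (camera adjusted p = 1.38e-07, and adjusted p = 0.688 with an estimated correlation), xkdJ at 1.26 and xhlB at 1.25 among them. Motility genes rose in 10 of 52 cases and fell in 1 (camera adjusted p = 2.05e-09, and adjusted p = 0.688 with an estimated correlation), with flhB at 1.41 and tlpC at -2.96 (SE 0.13). In the fatty acid list 6 of 15 rose, fabHA at 1.72 and fabF at 1.55 among them, and the desaturase gene desE fell by 1.31 (camera adjusted p = 0.00202, and adjusted p = 0.688 with an estimated correlation). In the glycolysis list 4 genes rose, cggR by 1.21, and the gluconeogenic genes gapB and pckA fell by 2.26 and 1.61 (camera adjusted p = 0.00423, and adjusted p = 0.688 with an estimated correlation). Extracellular protease genes fell in 5 of 8 cases, nprE by 2.30 and bpr by 1.74, and wprA rose by 1.53 (camera adjusted p = 0.0184, and adjusted p = 0.688 with an estimated correlation). The SigW, ribosomal protein, heat shock, PerR, cell wall and aromatic amino acid lists shifted up by medians of 0.20 to 0.91 with 0 to 3 genes called each (camera adjusted p = 2.66e-08 to 0.0462, and adjusted p = 0.673 to 0.787 with an estimated correlation). katA at 0.67, dhbB at 0.21 and hag at 0.86 were not called, and hag was called at 1.02 without NaCl+GB replicate 2 and at 1.01 with median scaling. The segment new_1117924_1118790 rose by 4.40 (SE 0.23). The segment new_1385938_1386023_c was not well above background in NaCl+GB and was at least 26.5-fold lower there (limma adjusted p = 1.37e-06).

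Scan days 1 and 2 held the NaCl arrays and scan days 3 and 4 the NaCl+GB arrays, so an offset between days cannot be told apart from the treatment, and with scan day or slide as a random block 1031 and 1002 features were called. With median scaling, which shifted all features by a median of 0.16, 549 of 1065 called features were higher, a share of 51.5% against 37.3%. The aromatic amino acid list lost its call without control replicate 3, any GB array, NaCl replicate 1 or NaCl+GB replicate 3 (camera adjusted p = 0.0502 to 0.174). Its median of 0.20 became 0.13 without NaCl replicate 1 and 0.51 without NaCl+GB replicate 2. The cell wall list lost its call without GB replicate 2 or 3, NaCl replicate 1 or NaCl+GB replicate 2 or 3 (camera adjusted p = 0.0507 to 0.0727).

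Of the 1871 features that salt had changed, 499 were called in the opposite direction when glycine betaine was added, and 140 in the same direction. The count of 140 fell to 47 with normexp background correction and 45 in the submitters' value table. Of the 858 that salt raised, 360 fell with glycine betaine, where independent lists would share 96.6. Features are not independent, however. Of 189 genes of the prophage SPbeta, 118 rose in NaCl vs control and 118 fell in NaCl+GB vs NaCl. How many of these are the same genes, and so part of the 360, was not counted. Of the 1013 that salt lowered, 139 rose, where independent lists would share 67.8. Simulated unchanged groups that share the NaCl arrays gave 0 features called in both comparisons. With nothing changed hardly any feature can be called, so this 0 does not measure what the shared arrays add to the 499. The covariance of the 2 sets of log2 fold changes was -0.42 against -0.03 in the simulation, and r across features was -0.29 against -0.50. The 3 NaCl arrays were too few to be split, so part of any excess may come from the shared arrays. Against the control, 1186 of the 1871 features were still called in the same direction in NaCl+GB. Over all 1871, the change relative to the control in NaCl+GB was a median of 0.81 times that in NaCl, with medians of 0.50 for features that salt had raised and 1.01 for those it had lowered. tasA, for example, moved from 3.59 ± 0.08 in the control to -3.92 ± 0.29 in NaCl and -0.07 ± 0.15 in NaCl+GB, and opuE from 0.44 ± 0.28 to 4.28 ± 0.31 and 2.53 ± 0.03. dhbB stood at 4.13 ± 0.23 in NaCl and 4.34 ± 0.40 in NaCl+GB, against 0.27 ± 0.29 in the control.

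**Figure D3:**
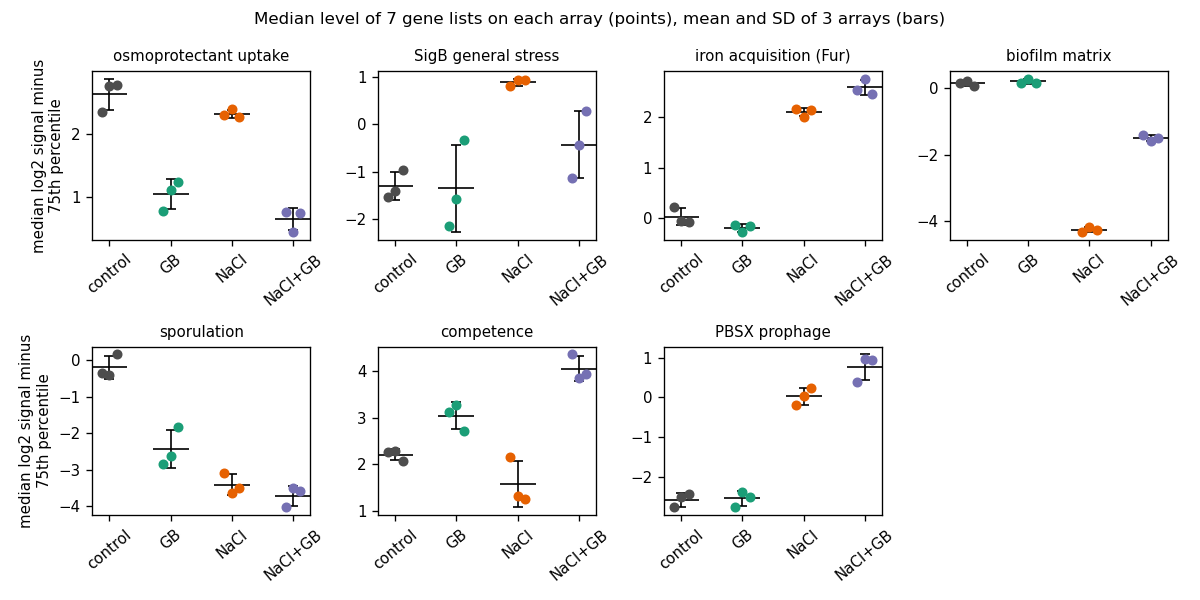
Median level of 7 gene lists per array (points, log2 signal minus the array's 75th percentile), 1 panel per list. Bars show mean and SD of 3 arrays per condition. Biofilm matrix had median changes per gene of -4.22 in NaCl vs control and 2.84 in NaCl+GB vs NaCl. Osmoprotectant uptake had 0.88 in NaCl vs control, but its plotted level did not rise.

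Cultures with both additions still differed from the unstressed control in 1659 features, 622 higher and 1037 lower. Without the fold minimum these were 2009 and 1671. PBSX, iron acquisition and competence genes stood above the control. Of the PBSX genes 26 of 26 were higher (camera adjusted p = 7.86e-15, and adjusted p = 0.670 with an estimated correlation), with xpf at 4.37 (SE 0.25) and xhlB at 4.33 (SE 0.20). tagC was the gene with the largest increase, at 6.73 (SE 0.21, limma adjusted p = 1.22e-09), followed by conD at 5.74 (SE 0.32), with nicK at 5.30 (SE 0.29) and conC at 5.28 (SE 0.29) also among the 10 largest. conD, conC and nicK belong to the conjugative element ICEBs1. Iron acquisition genes were higher in 21 of 29 cases (camera adjusted p = 1.76e-08, and adjusted p = 0.664 with an estimated correlation), with dhbE at 4.12 (SE 0.18), dhbC at 4.11 (SE 0.17) and dhbB at 4.07 (SE 0.21). Competence genes were higher in 18 of 20 cases (camera adjusted p = 1.46e-06, and adjusted p = 0.688 with an estimated correlation), comC by 2.85 (SE 0.26) and comK by 2.61 (SE 0.22). In the SigB regulon 37 genes were higher and 10 lower (camera adjusted p = 0.0193, and adjusted p = 0.859 with an estimated correlation), or 35 and 10 when adjusted over the list alone, with ydhK at 3.34 and clsB at -5.20. sigB itself, at 1.06, was no longer called without control replicate 2 or NaCl+GB replicate 3, and stood at 0.80 to 0.96 under the alternatives that ended its call. gsiB, at 2.24 with a limma adjusted p of 0.0504, was not called, but was called without control replicate 3 (3.11), NaCl+GB replicate 1 (2.72) or GB replicate 1 or 3 (2.24 each), and with normexp or median scaling (2.18 and 2.55). Its SD was 1.53 over the control arrays and 0.90 over the NaCl+GB arrays.

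Among osmoprotectant genes the 4 opuC genes were lower, at -2.58 to -2.48, and opuE was higher at 2.09 (SE 0.34). The other 8 uptake genes stood at -0.44 to 0.22 and were not called, nor was the list (camera adjusted p = 0.157, and adjusted p = 0.824 with an estimated correlation). gbsA and gbsB were higher by 1.34 and 1.27, gbsR and opcR stood at -0.67 and -0.47, and that list was not called (camera adjusted p = 0.723, and adjusted p = 0.878 with an estimated correlation). proH at 1.68 (SE 0.17) was higher, as was proJ, which stood at 0.83 ± 0.25 in the control and 2.33 ± 0.06 in NaCl+GB, and proA, proB and proI stood at 0.41 to 0.73, with proI called at 1.03 with median scaling (camera adjusted p = 0.0383, and adjusted p = 0.688 with an estimated correlation). Potassium and sodium transport genes were higher in 7 of 18 cases and lower in 1 (camera adjusted p = 0.00445, and adjusted p = 0.587 with an estimated correlation), with the sodium/proton antiporter genes mrpD and mrpC at 2.02 and 2.02 and the potassium importer gene kimA at -1.75. Sporulation genes were lower in 25 of 29 cases (camera adjusted p = 4.83e-10, and adjusted p = 0.688 with an estimated correlation), with spoIIIAG at -5.01 (SE 0.36) and spoVR at -4.93 (SE 0.25), and the largest decrease was that of spoIIID at -10.02 (SE 0.60, limma adjusted p = 7.56e-08). Biofilm matrix genes were lower in 21 of 22 cases (camera adjusted p = 1.41e-10, and adjusted p = 0.186 with an estimated correlation), tasA by 3.66 and sipW by 2.87. The lists of ribosomal proteins, glycolysis, sulfur amino acids, and purines and pyrimidines shifted up by medians of 0.38 to 0.90 with 0 to 6 genes called higher each (camera adjusted p = 2.17e-04 to 0.00857, and adjusted p = 0.688 to 0.789 with an estimated correlation). glnH stood at -6.41, katA at -1.53, vpr at -2.07 and alsD at 2.64.

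The groups shared no scan day, so an offset between days cannot be told apart from the treatments, and with scan day or slide as a random block 1641 and 1644 features were called. Scaling moved the balance, since with median scaling, which shifted all features by a median of 0.41, 1087 of 1937 called features were higher (56.1% against 37.5%), and with spike-in scaling, which shifted them by -0.16, 420 of 1670 (25.1%), against a shift of 0.11 with the scaling used throughout. The SigB list lost its call without NaCl+GB replicate 3 (camera adjusted p = 0.110).

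The interaction asked whether the effect of glycine betaine differed between the salt levels, as the change from NaCl to NaCl+GB minus the change from control to GB. It was called in 1198 features, 735 positive and 463 negative. Of the 703 features lower in GB vs control, 510 had a called positive interaction. Of the 703, 467 were also lower in NaCl and had too little room above background to fall by as much again. The lower limit of the signal can by itself give such features a positive interaction. Biofilm, competence and sporulation genes had positive interactions. In the biofilm list these were 19 of 22 genes (camera adjusted p = 7.44e-18, and adjusted p = 0.0832 with an estimated correlation), with sipW at 4.21 (SE 0.29, limma adjusted p = 3.78e-06) and tasA at 4.17 (SE 0.20). Competence gave 16 of 20 (camera adjusted p = 2.47e-06, and adjusted p = 0.688 with an estimated correlation), with comEA at 2.29 and comGG at 2.17. Sporulation gave 19 of 29 (camera adjusted p = 5.58e-08, and adjusted p = 0.688 with an estimated correlation), with spoIIIAD at 2.87 and spoIIQ at 2.86, genes that fell with glycine betaine alone and were already low in NaCl. The largest positive values were those of cdoA (BSU31140), a cysteine dioxygenase gene, at 4.65 (SE 0.25, limma adjusted p = 1.19e-06), and of the germination receptor gene gerBA at 4.44 (SE 0.35). cdoA stood at -0.62 ± 0.38 in the control and at -4.91 ± 0.15, -5.47 ± 0.12 and -5.12 ± 0.18 in GB, NaCl and NaCl+GB.

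The osmoprotectant uptake genes had no called interaction. All 13 lay at -0.41 to 0.36 with SE of 0.17 to 0.48, and camera did not call the list (camera adjusted p = 0.792, and adjusted p = 0.965 with an estimated correlation). proH and proJ at 0.75 and 0.76, and proA, proB and proI at -0.34 to 0.31, were not called either (camera adjusted p = 0.696, and adjusted p = 0.878 with an estimated correlation). gbsA at -1.06 and opcR at -1.17 were negative and called, while gbsB at -0.92 and gbsR at -0.95 were not (camera adjusted p = 0.00486, and adjusted p = 0.539 with an estimated correlation), and gbsA lost its call without GB replicate 2, NaCl replicate 2 or NaCl+GB replicate 1, with values of -1.11 to -0.92 over the alternatives that ended it. gbsR was called without control replicate 2, GB replicate 3, NaCl replicate 2 or NaCl+GB replicate 2, at -1.09 to -1.02, and gbsB with quantile normalization, at -1.15. All 4 proline catabolism genes were negative (camera adjusted p = 0.00210, and adjusted p = 0.505 with an estimated correlation), putP at -1.42 and putR at -1.37. In the SigB regulon 4 genes were positive and 16 negative (camera adjusted p = 1.10e-05, and adjusted p = 0.748 with an estimated correlation), or 3 and 13 when adjusted over the list alone. The protease list was negative in 4 genes, with nprE at -2.29, and positive in wprA at 1.98 (camera adjusted p = 0.0335, and adjusted p = 0.688 with an estimated correlation). PBSX was positive in 9 of 26 genes (camera adjusted p = 7.06e-06, and adjusted p = 0.688 with an estimated correlation). The SigW, purine and pyrimidine, and PerR lists shifted up by medians of 0.39 to 0.49, and the branched-chain and sulfur amino acid lists down by -0.45 to -0.26, with at most 4 genes called in each (camera adjusted p = 0.00536 to 0.0412, and adjusted p = 0.688 to 0.803 with an estimated correlation). Of the fixed examples dhbB was positive at 1.47 (SE 0.30), while gsiB at -1.97 (SE 1.29), sigB at -0.95 (SE 0.43), katA at 0.92 and hag at 0.29 were not called. Without GB replicate 1 gsiB and sigB were called, at -2.99 and -1.24, and katA was called without NaCl replicate 2 (limma adjusted p = 0.00258) and with quantile normalization, at 1.07. The largest negative values were those of yqiH at -4.04 (SE 0.29), yqiI at -3.90 (SE 0.37) and ispA at -3.85 (SE 0.23).

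An offset between scan days cancels in the interaction where the days hold both salt levels, and with scan day as a block 1250 features were called and 12 of the 13 called lists kept their call, the protease list being lost (camera adjusted p = 0.0523). With slide as a block 732 features were called, since only slides 1 and 6 held arrays of both salt levels and 1 array per group then carried it, and 16 named genes were then not called, with adjusted p of 0.0618 to 0.5001. These were bhlA, yvgO, yhcM, nhaX, yxbG, skiZ, ythQ, fldP, fldN, spoIIIAD, spoIIQ, glnQ, metI, metC, xpf and xkdW. Their SE were 1.22 to 2.14 times as wide, and 10 of the values were smaller and 6 larger than before. bhlA went from -3.73 (SE 0.60) to -3.25 (SE 1.17) and spoIIQ from 2.86 (SE 0.46) to 3.19 (SE 0.94). spoIIIAD went from 2.87 (SE 0.48) to 2.59 (SE 0.99) and fldP from 1.64 (SE 0.37) to 1.54 (SE 0.52). nhaX went from -3.01 (SE 0.87) to -2.34 (SE 1.27), metC from -1.52 (SE 0.48) to -1.12 (SE 0.98) and xpf from 1.41 (SE 0.35) to 1.01 (SE 0.60). Of the called lists, SigB moved from a median of -1.10 to -0.60 without GB replicate 3 and kept its call (camera adjusted p = 4.28e-04). SigW lost its call without that array, at 0.23 (camera adjusted p = 0.0599). The sulfur amino acid list lost it without replicate 2 of GB, NaCl or NaCl+GB, at -0.23 to -0.16 (camera adjusted p = 0.0842 to 0.1003). PerR lost it without control replicate 1, GB replicate 2 or 3, NaCl replicate 1 or NaCl+GB replicate 1 or 2 (camera adjusted p = 0.0640 to 0.0767).

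The effect of salt in the presence of glycine betaine, NaCl+GB against GB, was added after the scan days were known, because both groups were present on scan days 3 and 4. It called 1072 features, 426 higher and 646 lower. Of the 1871 features changed by salt alone, 834 were called here in the same direction and 14 in the opposite one. PBSX and iron acquisition genes rose here too. PBSX genes rose in 25 of 26 cases (camera adjusted p = 2.34e-23, and adjusted p = 0.252 with an estimated correlation), xpf by 4.67 (SE 0.25) and xhlB by 4.10 (SE 0.20). Iron acquisition genes rose in 18 of 29 cases and fell in 2 (camera adjusted p = 4.40e-12, and adjusted p = 0.252 with an estimated correlation), with dhbC at 5.35 (SE 0.17) and dhbB at 5.33 (SE 0.21). tagC rose by 5.71 (SE 0.21, limma adjusted p = 4.98e-09). Biofilm matrix genes fell in 21 of 22 cases (camera adjusted p = 1.48e-14, and adjusted p = 0.0597 with an estimated correlation), tasA by 3.34, and sporulation genes in 15 of 29 (camera adjusted p = 2.42e-04, and adjusted p = 0.753 with an estimated correlation), while the largest decreases were those of spoIIID at -6.31 (SE 0.60) and of wapA, which encodes a contact-dependent toxin, at -5.85 (SE 0.14, limma adjusted p = 3.77e-10). The SigB regulon rose in 18 of 104 genes, or 17 when adjusted over the list alone, and fell in 3 (camera adjusted p = 0.00152, and adjusted p = 0.790 with an estimated correlation). Competence genes rose in 5 of 20 cases (camera adjusted p = 3.87e-05, and adjusted p = 0.753 with an estimated correlation), comC by 1.84, and potassium and sodium transport genes in 10 of 18 (camera adjusted p = 4.81e-04, and adjusted p = 0.252 with an estimated correlation). Motility genes fell in 5 of 52 cases (camera adjusted p = 4.80e-10, and adjusted p = 0.671 with an estimated correlation).

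Osmoprotectant uptake genes rose in 8 of 13 cases (camera adjusted p = 0.0404, and adjusted p = 0.773 with an estimated correlation), with the opuA genes at 1.32 to 1.44, the opuB genes at 1.03 to 1.22 and opuE at 3.46 (SE 0.34), while the opuC genes at -0.94 to -0.82 and opuD at 0.17 were not called. opuBA was no longer called without replicate 1 or 2 of GB or replicate 1 or 3 of NaCl+GB (0.83 to 1.00 over the alternatives that ended it), and opuBC and opuBD stood at 0.94 and 0.98 with spike-in scaling. With that scaling the 4 opuC genes were called lower, at -1.14 to -1.03, and opuCB and opuCC were also called lower without GB replicate 1 or NaCl+GB replicate 3, opuCB at -1.11 and -1.03 and opuCC with limma adjusted p of 6.19e-04 and 5.29e-04. Without both scan 4 arrays opuBA and opuBC stood at 0.93 and 0.95. gbsA and gbsB rose by 1.31 and 1.29, while opcR at 0.94, called at 1.01 with median scaling, and gbsR at -0.33 were not called (camera adjusted p = 0.0501, and adjusted p = 0.609 with an estimated correlation), and proH and proJ by 3.44 and 3.47 (camera adjusted p = 0.0606, and adjusted p = 0.671 with an estimated correlation). The SigW and the purine and pyrimidine lists shifted up by medians of 0.33 and 0.35 with no gene called, and the cell wall list down by 0.29 with 5 genes lower (camera adjusted p = 0.0327 to 0.0455, and adjusted p = 0.753 to 0.826 with an estimated correlation).

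The salt effect was smaller with glycine betaine. Across 5860 features the changes with and without it correlated at r = 0.775, with a slope of 0.494, and their SD was 1.05 with and 1.64 without glycine betaine. The comparisons share no arrays, and simulated unchanged groups gave r = 0.012. Of the 1871 features called in NaCl vs control, 88.1% had a smaller change in NaCl+GB vs GB. This held for 82.4% of the raised and 93.0% of the lowered features. Of the 1013 lowered ones 570 were already lower in GB, and 467 of these had too little room above background for an equal fall. Their smaller change can come from the lower limit of the signal, and they also enter the slope and the SD. Within scan days 3 and 4, 99.8% of the called features, chosen on the same arrays, kept their direction on both days, the changes correlated at r = 0.912 across features, and 1102 features were called with scan day as a block. All 12 called lists kept their direction on both days, with medians that differed by at most 0.73, and 10 kept their call with scan day or with replicate number as a block, while osmoprotectant uptake and cell wall lost it (camera adjusted p = 0.0634 and 0.0585 with scan day, 0.0575 for both with replicate number). Of the other fixed examples katA fell by 1.28 (SE 0.13), hag stood at -0.45 and sigB at 0.78, and sigB was called only without GB replicate 3, at 1.16. gsiB, at 2.16 (SE 0.91) without a call, was called with either block at an unchanged 2.16, without control replicate 3 at 2.16 and without GB replicate 3 at 2.96. With spike-in scaling, which shifted all features by a median of -0.23, 315 of 1165 called features were higher, 27.0% against 39.7%. Without GB replicate 1 or NaCl+GB replicate 3 the lists SigB, osmoprotectant uptake, and purines and pyrimidines lost their call (camera adjusted p = 0.0506 to 0.0945), and the last had a median of 0.22 without GB replicate 1. SigW lost its call without GB replicate 3, at 0.21, or NaCl+GB replicate 1 (camera adjusted p = 0.249 and 0.0625). The cell wall list kept its call only without control replicate 2 or 3, GB replicate 1 or NaCl+GB replicate 2 (camera adjusted p of up to 0.0887 otherwise), and its median was -0.19 without GB replicate 3.

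**Figure D4:**
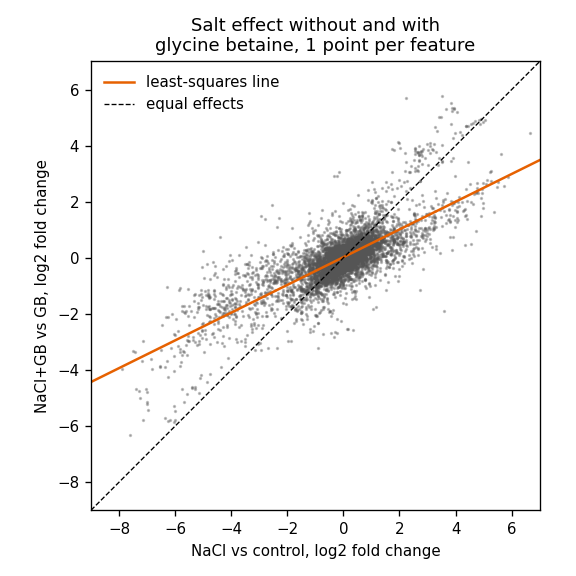
Log2 fold change of each tested feature in NaCl vs control (x axis) and in NaCl+GB vs GB (y axis), 1 point per feature, with 3 arrays per group. The least-squares line has a slope of 0.494 and lies below the dashed line of equal effects for features that salt raised.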

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

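The tests on genes lower with glycine betaine alone, on the choice of genes for the smaller salt effect, on the PBSX, ICEBs1 and tagC pattern, and on antisense signal were chosen only after those results had been seen, as were the splits with the additive effects removed, while the spike-in range and the other splits of the arrays were set out before. The effect of glycine betaine differed between the salt levels in 1198 features, by the interaction term of limma. Among the 735 positive ones were 510 of the 703 features lower in GB vs control. Of these 703, 467 had too little room to fall above background, so the lower limit of the signal bears on their interaction. The largest differences were those of cdoA (4.65), gerBA (4.44), yojB (4.29), yrrD (4.23), sipW (4.21), yqiH (-4.04), yqiI (-3.90), ispA (BSU13190, -3.85), bhlA (-3.73) and yvgO (-3.41). bhlA was not called with slide as a block (-3.25), and yvgO, with an SE of 1.09, lost its call at an adjusted p of 0.01, with slide as a block (-2.97), and without control replicate 1 or 2, GB replicate 2 or 3, NaCl replicate 2 or 3, or NaCl+GB replicate 1 or 2 (-3.42 to -2.64). The median interaction of the lists was -1.01 for glycine betaine synthesis from choline, -1.21 for proline catabolism, -1.10 for the SigB regulon (-0.60 without GB replicate 3), 0.39 for the SigW regulon (0.23 without GB replicate 3, not called) and 2.72 for biofilm matrix. It was -1.03 for extracellular proteases, 1.46 for competence, 1.71 for sporulation, -0.45 for branched-chain amino acids and -0.26 for sulfur amino acids (not called without replicate 2 of GB, NaCl or NaCl+GB, at -0.23 to -0.16). It was 0.49 for purines and pyrimidines, 0.44 for the PerR regulon (not called when any 1 of 6 arrays was left out) and 0.86 for PBSX. Probes that the design assigns to no feature gave antisense signal called higher in NaCl vs control over 174 genes.

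Of 100 drawn splits within the salt levels, 2 gave as many interaction calls as the real 1198, the real one included. The highest other split gave 2200 and the next 1101. The highest exchanged the NaCl and NaCl+GB arrays as wholes, so that it measured the mean effect of glycine betaine, which is also the difference between the scan days. Because of that effect the arrays of a salt level cannot stand in for one another, and these splits do not decide on the interaction. The additive effects of salt and glycine betaine were then taken out of the values. Of the same 100 splits 1, the real one, gave as many calls, and the highest other gave 1. Slides 2 to 5 each held arrays of 1 group only, so these splits cannot tell the interaction apart from differences between slides. The real interaction with scan day as a block was 1250. For each comparison of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. The real split (1871, 759, 1052, 1659 and 1072 features in NaCl vs control, GB vs control, NaCl+GB vs NaCl, NaCl+GB vs control and NaCl+GB vs GB) was 1 of 10, and the highest other gave 0 in each.

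The first pattern is the 703 features that were lower with glycine betaine alone, among them 23 of 29 listed sporulation genes. Of them 570 were also called lower in NaCl vs control, within the control's own scan days, where independent lists would share 121.5. The 2 comparisons share the control arrays, and simulated unchanged groups gave 0 features called in both and r = 0.49 across features against 0.60, with a covariance of 0.03 against 0.94. The 0 follows from groups in which nothing was changed and does not measure what the shared arrays add. The 3 control arrays were too few to be split, so part of the excess may come from them. An additive difference between scan days would lower the same features in NaCl+GB vs NaCl by a like amount, unless they were already near background in NaCl. For the 103 of the 570 that such a fall would have left at least 2-fold above the lowest signal well above background, the median there was -0.26 (quartiles of -0.69 and 0.00) against -1.54 in GB vs control. Such a difference alone would not give these values. The 103 were chosen on NaCl arrays that also enter NaCl+GB vs NaCl, however, and a rise with glycine betaine at high salinity could hide it. The other 467 of the 570 had less room to fall and decide nothing. Of all 703, 461 were well above background in all 4 groups, with medians of -0.41 in NaCl+GB vs NaCl and -1.77 in GB vs control. For the 133 that were not lower in NaCl the median was -0.996 against -1.33, which a difference between scan days would give, as would an effect of glycine betaine at both salt levels, so the 2 cannot be told apart there. Scaling was excluded as the whole source, since at least 85.1% of the 703 stayed lower under every scaling or background correction, and so was a single control culture, since at least 95.0% stayed lower without each control array. A scan-day difference that acts only on cultures without salt stays open, since the design has no such day with both treatments. A candidate explanation is that fewer cells entered sporulation with glycine betaine, which was not tested further.

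The second pattern is the smaller salt effect with glycine betaine, a median ratio of 0.431 over features called in NaCl vs control. A narrower signal range on the later scan days was excluded by the spike-in probes, whose SD on scan days 3 and 4 was 1.05 times that on scan days 1 and 2. Choosing features on the larger effect would lower the ratio in the same way from either side, but over features called in NaCl+GB vs GB the effect without glycine betaine was still 1.16 times that with it. The 2 directions differed against the control. Features that salt had raised stood in NaCl+GB at a median of 0.50 times their change in NaCl, but those it had lowered at 1.01 times, and 570 of these 1013 were already lower in GB. Of the 570, 467 had too little room above background for an equal further fall, so their smaller salt effect with glycine betaine decides nothing. A weaker effective stress with glycine betaine stays a hypothesis for the raised features, but not all raised lists followed it. By scan day, the iron acquisition list had medians of 1.38 and 1.33 in NaCl vs control and 1.69 and 1.92 in NaCl+GB vs GB. PBSX had 2.63 and 2.74, then 3.78 and 3.59. The SigB list did follow it, with 1.81 and 1.82, then 0.77 and 0.90. The hypothesis is not offered for the lowered features, whose change against the control was not smaller. Differences in growth rate at harvest were not measured here.

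The third pattern is the rise of PBSX, ICEBs1 and tagC with salt in the presence of glycine betaine, over 52 features. Scan day was excluded, since the median difference was 3.88 on scan 3 and 3.72 on scan 4. A shared response under LexA, the repressor of DNA damage genes, may account for it. Of 8 listed LexA regulon genes 3 were called higher, dinB at 2.01, dinK at 1.97 and dinL at 1.95. lexA stood at 0.94 (limma adjusted p = 1.80e-04), under the 2-fold minimum, and uvrA, uvrB, ruvA and ruvB at -0.02 to 0.19. recA, not among the 8, stood at 0.76 (limma adjusted p = 0.00134) without a call. These values leave the explanation open. In NaCl+GB vs GB 1 of the 6 genes first matched by name was called, and dinK and dinL were matched by locus only after the other values had been seen. Other inducers of these elements were not tested.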

How the results depend on the processing

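The alternatives of slide and scan day as random blocks, both scan 4 arrays left out, the submitters' value table, the scan-day block and left-out arrays on gene lists and all settings of NaCl+GB vs GB were chosen after the data were seen. No feature called both in the main fit and under a setting run by feature name changed direction, and no named gene was reversed. Features that lost their call were not checked for direction, other than the named genes. Without a fold minimum the counts were 3782 (NaCl vs control, 1908 of them higher), 2433 (GB vs control, 1317), 3069 (NaCl+GB vs NaCl, 1571), 3680 (NaCl+GB vs control, 2009), 2130 (interaction, 1105) and 2755 (NaCl+GB vs GB, 1256), with 1587 reversals, 545 features changed in the same direction by salt and glycine betaine and 2464 still called against the control, since the minimum removes small changes by construction. With slide as a block the interaction fell to 732, since only 4 of the 12 arrays then carried it. Every other total of called features and of reversals stayed within 1.5 times its value. By direction, the higher calls in GB vs control went from 56 to 196 with median and 29 with detected-probe scaling, those in NaCl+GB vs control from 622 to 1087 with median scaling, the negative interactions from 463 to 212 with slide as a block, the lower calls in NaCl+GB vs GB from 646 to 397 in the submitters' value table, and the features changed in the same direction by salt and glycine betaine from 140 to 47 with normexp and 45 in that table. Leaving out 1 array gave 1848 to 1908 features for NaCl vs control, 721 to 796 for GB vs control, 976 to 1096 for NaCl+GB vs NaCl, 1634 to 1686 for NaCl+GB vs control, 1158 to 1269 for the interaction, 1047 to 1110 for NaCl+GB vs GB and 469 to 527 reversals. Without both scan 4 arrays the counts were 1871, 791, 1021, 1694, 1209 and 1070, with 484 reversals. The submitters' value table gave 1598, 585, 814, 1382, 1018 and 715, with 418 reversals among unnamed features. Of the 160 list tests 69 were called by camera with the preset correlation, 0 by camera with an estimated correlation (13 at an unadjusted p under 0.05) and 104 by fry, of which 65 were shared with the 69, and fry does not compare a list with other genes. On leaving out an array 9 of the 69 list calls were lost at least once and 19 of the other tests were called at least once, with no called list reversed. A replicate block gave 1878, 770, 1087, 1690 and 1261 features in the planned contrasts, 529 reversals and 71 lists, of which 67 were shared. The arrays of these groups share only a number, and 4 of 6 arrays correlated best with their own number between control and GB, 2 between control and NaCl, 4 between control and NaCl+GB and 3 between NaCl and NaCl+GB. Of the named genes gsiB became called with it in NaCl+GB vs NaCl and NaCl+GB vs control. In NaCl+GB vs GB the block changed no call of a named gene other than gsiB or of a list other than those given. Of 386 named values in the planned contrasts, calls changed in 8 with normexp, 18 with quantile, 21 with median, 22 with spike-in and 11 with detected-probe scaling, 10 with the mean over probes, 13 at an adjusted p of 0.01, 31 without a fold minimum, 6 with slide as a random block, 6 without both scan 4 arrays, 2 with a replicate block, 1 with a trended robust spread and 35 on leaving out an array. Calls also changed in 18 of 153 with slide and 1 of 153 with scan day as a fixed block, and in 2 of 322 with only the 2 groups compared. The cause was not tested. Not run were the interaction with only 2 groups, fixed blocks for groups that share no slide or scan day, and the value table by name. Signal over background limits what was tested, since 5860 of the 5942 features passed the filter.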

Other observations

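The lists of the prophage SPbeta and the conjugative element ICEBs1 and the antisense tests were chosen after values had been seen. Genes of both elements rose with salt. Of 189 SPbeta genes, 118 rose and 10 fell in NaCl vs control (camera adjusted p = 3.28e-12, and adjusted p = 0.575 with an estimated correlation), with medians of 1.67 and 1.90 within scan days 1 and 2. In NaCl+GB vs NaCl, 118 of them fell and 2 rose (camera adjusted p = 3.31e-21, and adjusted p = 0.575 with an estimated correlation), the interaction was negative in 113 and positive in 1, or 114 and 2 when adjusted over the list alone (camera adjusted p = 2.66e-16, and adjusted p = 0.575 with an estimated correlation), and NaCl+GB differed from the control in 34 higher and 11 lower genes (camera adjusted p = 0.576, and adjusted p = 0.922 with an estimated correlation). In NaCl+GB vs GB 43 rose and 7 fell (camera adjusted p = 4.21e-04, and adjusted p = 0.842 with an estimated correlation), with medians of 0.31 and 0.42 on scan days 3 and 4, and GB vs control had 4 lower (camera adjusted p = 5.32e-04, and adjusted p = 0.842 with an estimated correlation). Of 25 ICEBs1 genes, 18 rose with salt (camera adjusted p = 3.36e-06, and adjusted p = 0.575 with an estimated correlation), with medians of 2.69 and 4.52 on scan days 1 and 2, and 18 rose in NaCl+GB vs GB (camera adjusted p = 1.18e-09, and adjusted p = 0.575 with an estimated correlation), with medians of 4.25 and 4.27 on scan days 3 and 4. In NaCl+GB vs NaCl 3 ICEBs1 genes rose and 1 fell, or 1 and 1 when adjusted over the list alone (camera adjusted p = 0.531, and adjusted p = 0.922 with an estimated correlation), 17 were higher in NaCl+GB than in the control (camera adjusted p = 2.62e-05, and adjusted p = 0.575 with an estimated correlation), and neither the interaction (camera adjusted p = 0.576, and adjusted p = 0.922 with an estimated correlation) nor GB vs control, with 1 lower gene or 0 when adjusted over the list alone (camera adjusted p = 0.576, and adjusted p = 0.922 with an estimated correlation), was called.

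Several fixed lists were not called by camera in any planned contrast. Mechanosensitive channel genes rose in 3 of 4 cases in NaCl vs control (camera adjusted p = 0.139, and adjusted p = 0.688 with an estimated correlation), with mscT at 1.79 and mscY at 1.21. Poly-gamma-glutamate genes rose in 4 of 5 cases (camera adjusted p = 0.0543, and adjusted p = 0.688 with an estimated correlation), capC by 1.81 and capB by 1.72. Of the glutamate and nitrogen genes 5 of 16 fell with salt (camera adjusted p = 0.219, and adjusted p = 0.688 with an estimated correlation), and glnH of the glutamine importer was lower in every comparison with the control, at -4.32, -3.37 and -6.41 in NaCl, GB and NaCl+GB. The tricarboxylic acid cycle had no called gene in any planned contrast and list medians of -0.10 to 0.37 (camera adjusted p of at least 0.0828). Respiration and fermentation genes rose in 5 and fell in 4 of 27 cases in NaCl+GB vs NaCl (camera adjusted p = 0.219, and adjusted p = 0.859 with an estimated correlation), with fnr at 2.50, alsS at 1.52 and ctaD of a terminal oxidase at -1.36. In NaCl vs control the cell wall list was not called (camera adjusted p = 0.0632, and adjusted p = 0.748 with an estimated correlation), although its 5 lower genes were dltA at -2.20, dltB at -2.06 and dltC, dltD and dltE at -2.04 to -2.01, which belong to 1 operon.

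Of 3797 genes with at least 5 unassigned probes on the opposite strand, 1540 had antisense signal that could be tested, and 49.7% of all unassigned probes were well above background over the 12 arrays. In NaCl vs control 174 were called higher and 327 lower, in GB vs control 29 and 98, in NaCl+GB vs NaCl 106 and 103, in NaCl+GB vs control 146 and 320, in the interaction 103 and 88, and in NaCl+GB vs GB 82 and 276. Antisense and sense changes correlated at r = -0.09 in NaCl vs control and -0.14 in NaCl+GB vs NaCl across genes, which are not independent replicates. In NaCl+GB vs NaCl the largest antisense increases were those of yhxD at 4.44 (sense -2.74), ybdN at 3.82 (sense -0.89) and gspA at 3.73 (sense -2.32). In NaCl vs control the largest increases were those of yukJ at 3.56, ybaS at 3.56 and yxbF at 3.52, and the largest decrease that of sspF at -4.18. Whether this signal is transcript or carries over from labelling was not tested.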
